A study of Mus musculus with 3 samples.

How the data were processed

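RNA from a mouse embryonic stem cell line was measured on 1-colour Illumina bead arrays, in undifferentiated cells and in reporter-positive cells obtained after treatment with Activin A or with Nodal. There were 3 groups with 2 arrays each, 6 arrays in all. The design text gives 2 replicates for each group, while the notes on the individual samples read otherwise; the array columns analysed here are 2 per group. Groups were taken from the sample titles, and each array column was assigned by its name. Per the labels, at least 100 ng of total RNA was amplified into biotin-labelled cRNA. The array model, the scanner software and its version are not given in the sources used here.

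The deposited table of individual arrays holds a signal intensity for each of 25697 probes, without normalization or background subtraction. The deposited detection p-values stand beside each signal, in steps of 1/798 as judged from the values. A second deposited table holds the submitters' mean intensity of each group, per the labels. It is on a linear scale, with medians of 19.3 (Activin), 19.2 (Nodal) and 19.1 (undifferentiated) and with 6837 to 6908 probes below 0. Its values correlated with the mean raw signal of the same group across probes (r from 0.998 to 0.999), so the scale is linear and a background was subtracted; the normalization behind it stays unknown. It served only as an alternative source of log2 differences.

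Background was estimated from the detection p-values and corrected with the neqc function of limma 3.58.1 in R 4.3.3, with an offset of 16, quantile normalization and a log2 transformation. A probe was kept where its detection p was under 0.05 on both arrays of at least 1 group, which left 13775 probes. Each gene was represented by its kept probe with the highest mean log2 intensity, which gave 10050 genes. Of these, 7410 had 1 kept probe. Among the other 2640, probes of the same gene were called in opposite directions for 91 genes (Activin against undifferentiated), 96 genes (Nodal against undifferentiated) and 0 genes (Nodal against Activin). Gene symbols came from the array table and were updated through the RefSeq genes of assembly GRCm38.p6, used for names only. Of the probes, 17548 carried a current symbol, 7082 matched by a synonym, 1040 kept the symbol of the table, and 27 carried a symbol that a spreadsheet had turned into a date or number and stayed unnamed. No genome build is given in the sources used here, so no coordinates are reported.

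Group means were fitted to all 6 arrays with lmFit and eBayes of limma, so that the groups shared 1 estimate of the spread, with 3 residual degrees of freedom and 6.29 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. An adjusted p given for a gene comes from this fit unless another setting or a fit over probes is named. Where a gene was not detected on any array of the dimmer group, the change is given as a bound ("at least N-fold"): the brighter group's mean against the mean, per array, of the higher of the gene's own signal and the lowest detected signal. For Dusp2 and Krt14 the fitted difference is given beside the bound.

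Gene lists, 22 in all, were tested with camera of limma, with a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment over the 66 pairs of list and comparison. Camera with an estimated correlation stood beside it. Of the 343 genes listed, 325 had a probe and 244 were tested. The lists covered pluripotency, formative and primed epiblast, definitive endoderm, primitive streak, mesoderm, blood and endothelium, visceral endoderm, parietal endoderm, foregut, midgut and hindgut, liver and pancreas, Nodal and Activin target genes, Nodal and Activin pathway components, BMP and WNT response and ligands, neural ectoderm, fibroblast feeder, epithelial and mesenchymal state, cell cycle, stress and immediate early genes, glycolysis and hypoxia, and lipoprotein and retinoid handling. Spink3 of the visceral endoderm list is Spink1 in the current naming.

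Groups, tests, thresholds, lists, the alternatives of the processing and the rule for named genes were chosen before the data were examined. By that rule the genes to be named were, for each comparison, the 10 genes that rose most and the 10 that fell most among genes past the threshold whose arrays did not overlap and whose symbol is not a predicted or clone name, up to 4 members of each list with the smallest p, and a fixed set of 24 marker genes. Not all of them are printed. Other list members, and genes named to spell out a small count, were chosen after their values were seen. Some single-gene results are not reported here. Alternatives were other background corrections, median scaling, other filters, another variance model, only the arrays compared, the mean over probes, a replicate block, stricter thresholds, other set tests and leaving out each array in turn. Leaving out an array meant filtering probes and choosing the probe of each gene anew, which changed the probe of some genes, as another background correction can. For named genes and list members among these, the setting was run again with the first probe kept, which was chosen after seeing the data. A slide block was among the alternatives and was not run, since the columns analysed here carry no slide.

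The steps were tested on simulated data in which 200 genes were changed by known amounts. For Nodal against Activin, 50.7% of genes changed by 0.5 log2, 78.6% of those changed by 1 and 96.7% of those changed by 2 were recovered with the right sign, and 4.08% of calls were false. For Activin against undifferentiated the shares were 44.2%, 86.5% and 96.7%, with 8% false calls. For Nodal against undifferentiated they were 50.6%, 85.5% and 98.3%, with 4.64% false calls. Camera called 3 of 100 unchanged lists at an unadjusted p under 0.05. The simulated noise was independent between genes and arrays, so these shares do not cover correlated genes or differences between cultures. The comparisons with undifferentiated cells also called far more genes than were changed here (75.1% with Activin and 75.6% with Nodal), so the shares need not carry over. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.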

Results

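The Sox17-GFP line is a mouse embryonic stem cell line that carries a fluorescent reporter of Sox17, a transcription factor of the endoderm. Undifferentiated cells were kept with mouse embryonic fibroblasts as feeders, in 15% serum with the cytokine LIF. Reporter-positive cells were obtained after 7 days in 5% serum. The ligand was either human Activin A at 50 ng/ml or mouse Nodal at 1000 ng/ml, both recombinant proteins of the TGF-beta family. The protocol gives 6 to 8 days. The doses differ, so ligand and dose changed together between the endoderm groups. Each group was measured on 2 arrays, and nothing in the labels says that these came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical.

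The signal summed over probes lay between 10097581 and 11999128 per array, and between 49.3% and 50.6% of its 25697 probes were detected at a detection p under 0.05. Median signals lay between 55.2 and 60.9. Of the genes, 10050 were tested. Across these genes, which are not independent replicates, the 2 arrays of a group correlated at r between 0.9969 and 0.9978. Arrays of the Activin and the Nodal group correlated at r between 0.9938 and 0.9956, and arrays of either endoderm group correlated with undifferentiated arrays at r between 0.845 and 0.850. The median absolute log2 difference was 0.109 between the Activin arrays and 0.0887 between the Nodal arrays. Activin replicate 1 lay as near the Nodal arrays (0.107 and 0.109) as its own replicate, and Activin replicate 2 lay farther from them (0.139 and 0.128). The number of arrays limits the precision, and the median standard error of a log2 difference was 0.0963.

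The first comparison asked which genes distinguished Activin-derived endoderm from undifferentiated cells. All 19 tested genes of the definitive endoderm list rose (camera adjusted p = 8.81e-11; adjusted p = 0.0893 with an estimated correlation). Gsc, a homeobox gene of the organizer and anterior endoderm, rose by 7.59 log2 (SE 0.09; detected on 1 of 2 undifferentiated arrays), and Cxcr4, a chemokine receptor used to isolate endoderm, by 5.65 log2 (SE 0.10). Foxa1 and Foxa2, forkhead factors of the endoderm, were at least 48.6-fold and at least 16.4-fold brighter. Sox17 rose by 5.35 log2 (SE 0.09), but it is the reporter gene used to choose the cells, so its rise is not a finding. Pluripotency genes fell: 19 of 21 fell and 2, Lin28a (0.62 log2) and Sall4 (0.72 log2), rose (adjusted p = 9.53e-09; adjusted p = 0.0893 with an estimated correlation). Esrrb fell by 7.32 log2 (SE 0.09), Pou5f1 by 5.85 (SE 0.13) and Nanog by 4.81 (SE 0.12), all transcription factors of the pluripotent state. In total 7550 genes passed the threshold in limma, 3739 higher and 3811 lower in Activin endoderm, of which 1463 and 1285 changed at least 2-fold. Median scaling in place of quantile normalization moved the median of all genes by 0.103 log2 here and by 0.107 in the Nodal comparison, so small changes hold only relative to that shift. With that scaling 4090 genes were higher and 3177 lower in Activin endoderm, and 4174 higher and 3204 lower in Nodal endoderm.

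Among single genes, Fgf5, a growth factor of the epiblast, was at least 149-fold brighter in Activin endoderm. Lhx1, a homeobox gene of the streak and anterior endoderm, was at least 125-fold brighter. Krt18, an epithelial keratin, rose by 6.98 log2 (SE 0.09). Ooep, an oocyte-expressed gene, fell by 8.00 log2 (SE 0.10). Gbx2 fell by 7.05 (SE 0.09), and Klf2 and Lyz1 were at least 90.4-fold and at least 122-fold brighter in undifferentiated cells. The adjusted p values of these 7 changes lay between 2.55e-11 and 3.67e-11.

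Other lists moved with Activin as well. Of 13 primitive streak genes 11 rose and 2 fell (adjusted p = 0.000223; adjusted p = 0.243 with an estimated correlation), among them T and Mixl1, at least 36.7-fold and at least 35.7-fold brighter, while Fgf17 and Wnt3a fell. Of 13 foregut genes 11 rose and 2, Sox2 and Irx2, fell (adjusted p = 0.0014; adjusted p = 0.231 with an estimated correlation). The BMP list rose in 11 of 14 genes and fell in Bmp4 and Grem1 (adjusted p = 0.0037; adjusted p = 0.207 with an estimated correlation), the WNT list rose in 10 of 12 and fell in Ccnd1 and Notum (adjusted p = 0.00334; adjusted p = 0.201 with an estimated correlation), and Nodal and Activin target genes rose in 8 of 12 and fell in 1, Tdgf1 (adjusted p = 0.00252; adjusted p = 0.188 with an estimated correlation). Formative and primed epiblast genes rose in 7 of 9 and fell in 2, Pou3f1 among them (adjusted p = 0.019; adjusted p = 0.216 with an estimated correlation). Epithelial and mesenchymal genes rose in 10 of 13 and fell in 1, Zeb1 (adjusted p = 0.0208; adjusted p = 0.243 with an estimated correlation), and parietal endoderm genes rose in 11 of 16 and fell in 5, Dab2, Lama1, Nid1, Sox7 and Thbd (adjusted p = 0.0409; adjusted p = 0.291 with an estimated correlation), a call that ended without Activin replicate 2 (adjusted p = 0.0536). All 15 cell cycle genes fell, among them the replication licensing genes Mcm3 (-1.63 log2) and Mcm5 (-1.62 log2) (adjusted p = 0.000273; adjusted p = 0.152 with an estimated correlation). Stress and immediate early genes fell in 9 of 14 and rose in 1, Jun (adjusted p = 0.01; adjusted p = 0.201 with an estimated correlation). Without genes shared by lists, the calls of the WNT (adjusted p = 0.0731), target gene (adjusted p = 0.244), formative and primed (adjusted p = 0.0731), epithelial and mesenchymal (adjusted p = 0.0658) and parietal endoderm (adjusted p = 0.0954) lists ended, and the primitive streak list kept too few genes to be tested in any comparison.

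Fibroblast feeder genes were brighter in the undifferentiated cultures, which contained feeders: 10 of 14 fell in Activin endoderm and 4, Ccn1, Mmp2, Pdgfrb and Acta2, rose (adjusted p = 0.0292; adjusted p = 0.263 with an estimated correlation). The rise of Acta2 (0.28 log2) rests on 1 of its 4 kept probes, since the other 3 gave 0.03, -0.02 and 0.14 (adjusted p over probes = 0.835, 0.826 and 0.33). Lox was at least 22.1-fold brighter in undifferentiated cultures, and Fbln2 fell by 2.29 log2 (SE 0.09). The same cultures were the reference for every list above. The lists of visceral endoderm (6 rose and 5 fell of 14, adjusted p = 0.837), lipoprotein and retinoid handling (6 and 4 of 11, adjusted p = 0.66), liver and pancreas (5 and 1 of 7, adjusted p = 0.114), mesoderm (6 and 5 of 11, adjusted p = 0.8) and blood and endothelium (3 and 4 of 7, adjusted p = 0.713) did not pass. Nor did midgut and hindgut (3 and 4 of 8, adjusted p = 0.837), neural ectoderm (2 and 2 of 7, adjusted p = 0.815), glycolysis and hypoxia (3 and 9 of 15, adjusted p = 0.196) or Nodal and Activin pathway components (9 and 4 of 14, adjusted p = 0.285). The midgut and hindgut list had a median of -0.36 and a mean of 0.43 log2, and the visceral endoderm list a median of -0.02 and a mean of 0.44. Adjusted over the list alone, the counts were the same except that 5 midgut and hindgut genes fell.

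**Figure D1:**
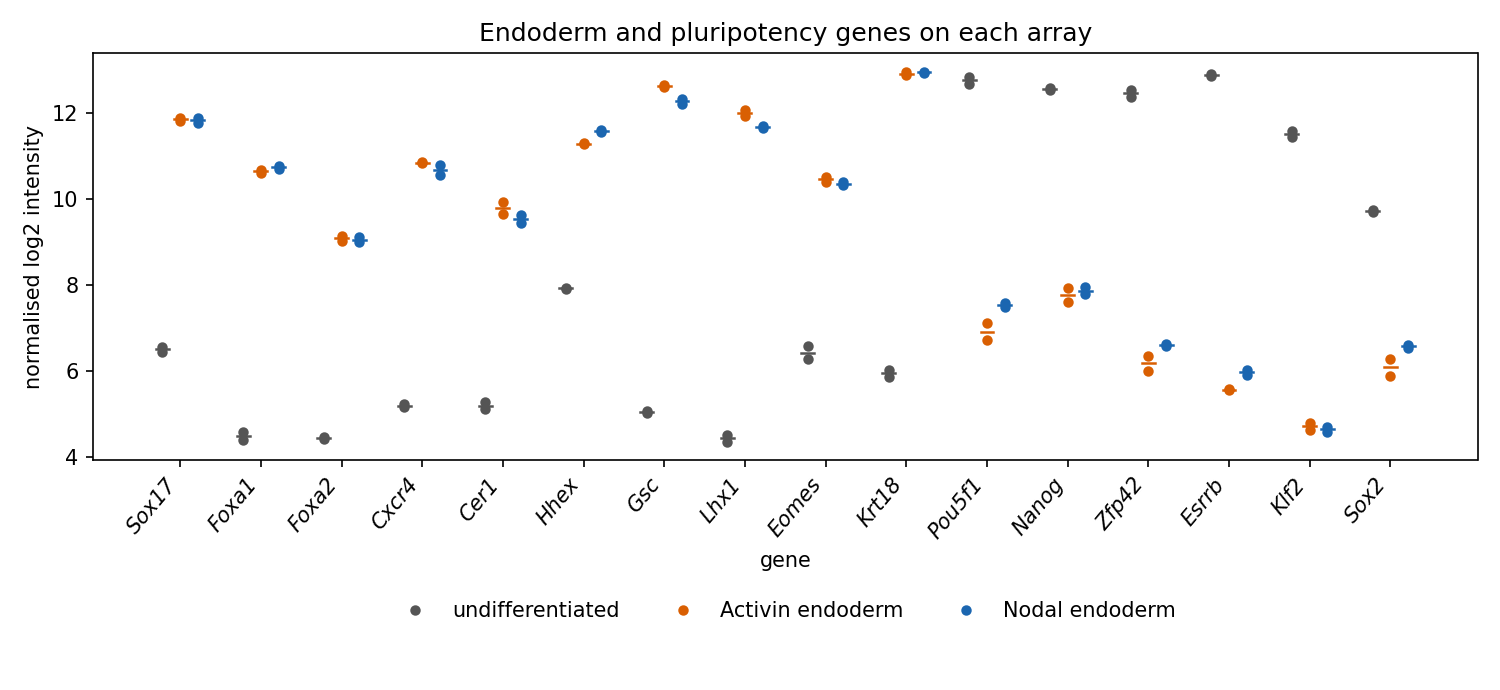
Normalised log2 intensity (y axis) of endoderm and pluripotency genes (x axis), with 1 point for each of the 2 arrays of a group and a bar at the group mean. Sox17 lay at 6.51 in undifferentiated cells, 11.86 in Activin endoderm and 11.85 in Nodal endoderm, and the pluripotency gene Esrrb at 12.90, 5.58 and 5.98.

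The next comparison set Nodal-derived endoderm against undifferentiated cells. The definitive endoderm list again rose in all 19 genes (adjusted p = 8.81e-11; adjusted p = 0.0893 with an estimated correlation), with Gsc up by 7.23 log2 (SE 0.09), Cxcr4 by 5.50 (SE 0.10) and Foxa1 and Foxa2 at least 51.6-fold and at least 16.1-fold brighter. Sox17, the reporter gene, rose by 5.33 log2 (SE 0.09). Pluripotency genes fell in 19 of 21 and rose in 2, Lin28a (0.63 log2) and Sall4 (0.70 log2) (adjusted p = 1.26e-08; adjusted p = 0.0893 with an estimated correlation). Gbx2 fell by 7.36 log2 (SE 0.09), Esrrb by 6.92 (SE 0.09) and Pou5f1 by 5.23 (SE 0.13). Fgf5 was at least 133-fold brighter, Lhx1 was at least 99.1-fold brighter, and Ttr, a carrier of thyroid hormone and retinol-binding protein, rose by 6.03 log2 (SE 0.22; detected on 1 of 2 undifferentiated arrays). In total 7602 genes passed the threshold in limma, 3765 higher and 3837 lower, of which 1507 and 1317 changed at least 2-fold.

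With Nodal, primitive streak genes rose in 11 of 13 and fell in Fgf17 and Wnt3a (adjusted p = 0.000281; adjusted p = 0.252 with an estimated correlation), foregut genes rose in 11 of 13 and fell in Sox2 and Irx2 (adjusted p = 0.00119; adjusted p = 0.231 with an estimated correlation), and parietal endoderm genes rose in 12 of 16 and fell in 3, Nid1, Sox7 and Thbd (adjusted p = 0.00545; adjusted p = 0.242 with an estimated correlation). Liver and pancreas genes rose in 6 of 7 and fell in 1, Neurog3 (adjusted p = 0.0491; adjusted p = 0.243 with an estimated correlation), a call that ended without undifferentiated replicate 2 (adjusted p = 0.0518). The BMP list (11 rose and 2 fell of 14, adjusted p = 0.00441), the WNT list (10 and 2 of 12, adjusted p = 0.0053), target genes (7 and 2 of 12, adjusted p = 0.00975), formative and primed epiblast (7 and 1 of 9, adjusted p = 0.019) and the epithelial and mesenchymal list (9 and 3 of 13, adjusted p = 0.0409) passed as well. With an estimated correlation their adjusted p values were 0.207, 0.201, 0.201, 0.216 and 0.263. The last call ended without undifferentiated replicate 1 (adjusted p = 0.0505). Without genes shared by lists, those of the WNT (adjusted p = 0.0954), target gene (adjusted p = 0.586), formative and primed (adjusted p = 0.0731) and epithelial and mesenchymal (adjusted p = 0.0954) lists ended, and the liver and pancreas list kept too few genes to be tested. All 15 cell cycle genes fell (adjusted p = 0.000281; adjusted p = 0.152 with an estimated correlation), as did 11 of 14 stress and immediate early genes, with 1, Jun, that rose (adjusted p = 0.0027; adjusted p = 0.188 with an estimated correlation). Feeder genes fell in 11 of 14 and rose in 3, Ccn1, Mmp2 and Pdgfrb (adjusted p = 0.00975; adjusted p = 0.243 with an estimated correlation), with Lox at least 22.3-fold and Thy1 at least 14.6-fold brighter in undifferentiated cultures.

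The visceral endoderm list rose in 9 of 14 genes and fell in 3, Amn, Rhox5 and Trf, and as a list it did not pass (adjusted p = 0.0589), although it did without Activin replicate 1 (adjusted p = 0.0496) or Nodal replicate 1 (adjusted p = 0.0441), and against a background of all named probes (adjusted p = 0.0121). Lipoprotein and retinoid handling (7 rose and 3 fell of 11, adjusted p = 0.21), mesoderm (6 and 5 of 11, adjusted p = 0.837), blood and endothelium (3 and 4 of 7, adjusted p = 0.744), midgut and hindgut (3 and 3 of 8, adjusted p = 0.979) and neural ectoderm (2 and 1 of 7, adjusted p = 0.713) did not pass either. Glycolysis and hypoxia (3 and 9 of 15, adjusted p = 0.199) and pathway components (9 and 4 of 14, adjusted p = 0.234) likewise did not. The midgut and hindgut list had a median of -0.19 and a mean of 0.51 log2. Adjusted over the list alone, the counts were the same.

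The comparison named in the title of the series set Nodal-derived against Activin-derived endoderm. Visceral endoderm genes were higher in Nodal endoderm: 10 of 14 rose and 0 fell (adjusted p = 1.27e-16; adjusted p = 0.0893 with an estimated correlation). Ttr was higher by 3.08 log2 (SE 0.22, 95% interval 2.59 to 3.56, adjusted p = 0.000176), the apolipoprotein Apoa1 by 2.25 (SE 0.11, interval 2.01 to 2.48, adjusted p = 3.48e-05), the endocytic adaptor Dab2 by 1.45 (SE 0.10), Amn, a partner of the receptor cubilin, by 1.33 (SE 0.08), and the nuclear receptor Hnf4a by 1.16 (SE 0.10). Of the 10, 8 passed under every setting in which they were tested, and Rbp4 and Spink1 did not. Ttr, Apoa1, Apoa2 and Apom were not tested with detection on all 6 arrays. Lipoprotein and retinoid genes, some of them in the same list, rose in 6 of 11 with 0 that fell (adjusted p = 1.67e-06; adjusted p = 0.133 with an estimated correlation), and 3 of these 6, Apoa1, Apoc1 and Apom, passed under every setting. Parietal endoderm genes rose in 7 of 16 with 0 that fell (adjusted p = 9e-07; adjusted p = 0.154 with an estimated correlation), and among these Dab2 alone passed under every setting. Adjusted over the list alone, 11 visceral, 6 lipoprotein and retinoid and 9 parietal endoderm genes rose.

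Primitive streak genes were lower in Nodal endoderm, with 3 of 13 that fell and 0 that rose (adjusted p = 1.61e-08; adjusted p = 0.201 with an estimated correlation), or 9 that fell adjusted over the list alone. T, a T-box factor of the streak, was lower (-1.12 log2, SE 0.11, interval -1.37 to -0.87, adjusted p = 0.00118), as was the homeobox gene Mixl1 (-0.78, SE 0.09, adjusted p = 0.00237). The third was Fgf17 (-0.58, SE 0.09), whose call ended without Activin replicate 2 (-0.51, adjusted p = 0.0755), Nodal replicate 1 (-0.62, adjusted p = 0.0588) or Nodal replicate 2 (-0.53, adjusted p = 0.0888), and with the mean over probes (-0.30, adjusted p = 0.133). Target genes of the pathway fell in 1 of 12, again Mixl1 (adjusted p = 0.000223; adjusted p = 0.152 with an estimated correlation), and in 3 adjusted over the list alone. The probes listed under the older symbols Ebaf and Leftb, which the naming source gives to both Lefty genes, differed by -0.61 and -0.50 log2. The call of Ebaf ended without Activin replicate 2 (adjusted p = 0.0551) or Nodal replicate 1 (adjusted p = 0.0585), and that of Leftb without Activin replicate 2 (adjusted p = 0.175), Nodal replicate 1 (adjusted p = 0.141) or Nodal replicate 2 (adjusted p = 0.152) and without the filter on dim probes (adjusted p = 0.0818). WNT genes fell in 3 of 12, Axin2, Ccnd1 and Lgr5 (adjusted p = 0.0216; adjusted p = 0.231 with an estimated correlation), or 6 adjusted over the list alone. The call of each of the 3 ended in several settings, and that of the list ended without Nodal replicate 1 (adjusted p = 0.119). Without genes shared by lists, the calls of the WNT (adjusted p = 0.141) and target gene (adjusted p = 0.105) lists ended. Feeder genes fell in 2 of 14, both before and after adjustment over the list alone (adjusted p = 0.0147; adjusted p = 0.243 with an estimated correlation): Tagln fell by 0.75 log2 and Acta2 fell by 0.55, both also genes of smooth muscle. The list's call ended against a background of all named probes (adjusted p = 0.0546), and that of Acta2 without Activin replicate 2 (adjusted p = 0.0962), Nodal replicate 1 (adjusted p = 0.0702) or Nodal replicate 2 (adjusted p = 0.1).

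Pluripotency genes rose in 5 of 21 and fell in 1, Zfp57 (adjusted p = 0.000323; adjusted p = 0.152 with an estimated correlation), or in 11 and 2 adjusted over the list alone. Dppa5a was higher in Nodal endoderm by 1.17 log2 (SE 0.13, adjusted p = 0.00235) and Fbxo15 by 0.84 (SE 0.10, adjusted p = 0.00384), and these 2 passed under every setting. Pou5f1 was higher by 0.62 (SE 0.13, adjusted p = 0.0357), a call that ended without Activin replicate 1 (adjusted p = 0.113), Nodal replicate 1 (adjusted p = 0.194), Nodal replicate 2 (adjusted p = 0.111) or undifferentiated replicate 2 (adjusted p = 0.0525), without the filter on dim probes (adjusted p = 0.142) and with the mean over probes (adjusted p = 0.0695). The calls of Tbx3, Esrrb and Zfp57 ended too, each without Activin replicate 2 (adjusted p for Tbx3 = 0.0674 and for Zfp57 = 0.0675) among other arrays. With 1 array left out, the differences lay between 0.42 and 0.81 for Pou5f1, 0.52 and 0.62 for Tbx3 and 0.33 and 0.45 for Esrrb, against 0.62, 0.57 and 0.40 with all arrays. The difference of Esrrb was 0.22 (adjusted p = 0.0996) with normexp by maximum likelihood and 0.27 (adjusted p = 0.0708) without a background correction, which ended its call as well. Nanog differed by 0.11 (SE 0.12, interval -0.15 to 0.37, adjusted p = 0.733).

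The definitive endoderm list did not pass, with 0 of 19 genes that rose or fell in limma (adjusted p = 0.713), although adjusted over the list alone, and at an unadjusted p under 0.05, 5 rose and 2 fell. The difference was -0.03 log2 for Foxa2 (interval -0.23 to 0.18), -0.16 for Cxcr4 (interval -0.38 to 0.06) and -0.10 for Eomes (interval -0.34 to 0.15), so these intervals exclude a 2-fold difference. Sox17, also among the 19 genes, differed by -0.02 log2 (interval -0.22 to 0.19). Both groups were chosen by its reporter, so its small difference is not a finding. No cell cycle gene of 15 passed (adjusted p = 0.952), and 0 did so adjusted over the list alone or at an unadjusted p under 0.05. The foregut list was higher as a list (adjusted p = 0.0146; adjusted p = 0.269 with an estimated correlation) with 0 of 13 genes past the threshold, 6 that rose adjusted over the list alone and 7 at an unadjusted p under 0.05; the list's call ended without Activin replicate 2 (adjusted p = 0.0741), without genes shared by lists (adjusted p = 0.103) and with fry (adjusted p = 0.0546). Afp was not detected on any array and was not tested.

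The other lists did not pass. Of 14 BMP genes Id2 rose and Nog fell (adjusted p = 0.21). Of 7 liver and pancreas genes Ttr and Hnf4a rose and Nkx6-1 and Sox9 fell (adjusted p = 0.408). Pdgfra rose among 11 mesoderm genes (adjusted p = 0.972), Cdx2 rose among 8 midgut and hindgut genes (adjusted p = 0.374), and Lmo2 fell among 7 blood and endothelium genes (adjusted p = 0.267). Apart from Ttr and Hnf4a, each of these single calls ended without Activin replicate 2 among other arrays. The lists of pathway components (adjusted p = 0.66), epithelial and mesenchymal state (adjusted p = 0.129), formative and primed epiblast (adjusted p = 0.408), neural ectoderm (adjusted p = 0.972), stress and immediate early genes (adjusted p = 0.0891) and glycolysis and hypoxia (adjusted p = 0.907) held 0; at an unadjusted p under 0.05 at most 3 genes of each rose and at most 3 fell. Without Activin replicate 2 the blood and endothelium and the stress lists passed (adjusted p = 0.0458 for both), and without Nodal replicate 1 the epithelial and mesenchymal list did (adjusted p = 0.0335). The median and the mean differed in sign for the definitive endoderm, formative, mesoderm and neural lists, all within 0.1 log2 of 0. Adjusted over the list alone, 3 BMP genes rose and 4 fell, 2 stress genes fell, and at most 2 genes moved in either direction in each of the rest.

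Among single genes higher in Nodal endoderm were Soat2, a cholesterol-esterifying enzyme (1.82 log2, SE 0.12, adjusted p = 0.000176), the peptidase Dpp4 (1.63, SE 0.09, adjusted p = 4.75e-05), the anion transporter Slc13a4 (1.60, SE 0.16), and the peptide hormone genes Sst (1.59, SE 0.16) and Ghrl (1.45, SE 0.09; detected on 1 of 2 Activin arrays). Ghrl had another kept probe with a smaller difference (0.75 log2, adjusted p over probes = 0.00535). Leaving out either Nodal array or the background correction put that probe in place of the first, with differences of 0.74 without Nodal replicate 1, 0.74 without Nodal replicate 2 and 0.47 without the correction. With the first probe kept, a setting chosen after seeing the data, they were 1.41, 1.48 and 0.98, all past the threshold. With another background model, normexp by maximum likelihood, the differences were 1.14 log2 for Soat2, 0.98 for Dpp4, 1.04 for Sst, 0.78 for Ghrl, 0.71 for Muc13, 0.51 for Fbxo15 and -0.39 for Tagln, all past the threshold. Muc13 was higher by 1.26 log2 (SE 0.11) with the probe used, and its other kept probe differed by 0.28 (adjusted p over probes = 0.351). Its call ended where leaving out Nodal replicate 1 (0.45, adjusted p = 0.18) or Nodal replicate 2 (0.10, adjusted p = 0.842) also exchanged the probes. With the probe kept, again chosen after seeing the data, it passed without either array (adjusted p = 0.00808 and 0.00406; 1.30 log2 without Nodal replicate 2). Lower in Nodal endoderm were the neuropeptide gene Gal (-1.13, SE 0.10, adjusted p = 0.000854), the cytokine gene Il4 (at least 2.14-fold) and the probes listed as Defa26 (-1.27), Defcr-rs10 (-1.26) and Defa31 (-1.20). These last belong to the alpha-defensin family, whose members are so alike that the gene measured is uncertain.

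In total 328 genes passed the threshold in limma, 178 higher and 150 lower in Nodal endoderm, and 26 of them changed at least 2-fold (17 higher, 9 lower). At an unadjusted p under 0.05 there were 1614. For 9973 genes (99.2%) the 95% interval lay within a 2-fold difference. The 2 arrays of each group were fully separated for 46% of genes, where chance gives 33.3%. The count was 87 without Activin replicate 2, 83 without Nodal replicate 1 and 95 without Nodal replicate 2. It was 528 with another background model, 114 without the filter on dim probes and 202 with detection on all 6 arrays.

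**Figure D2:**
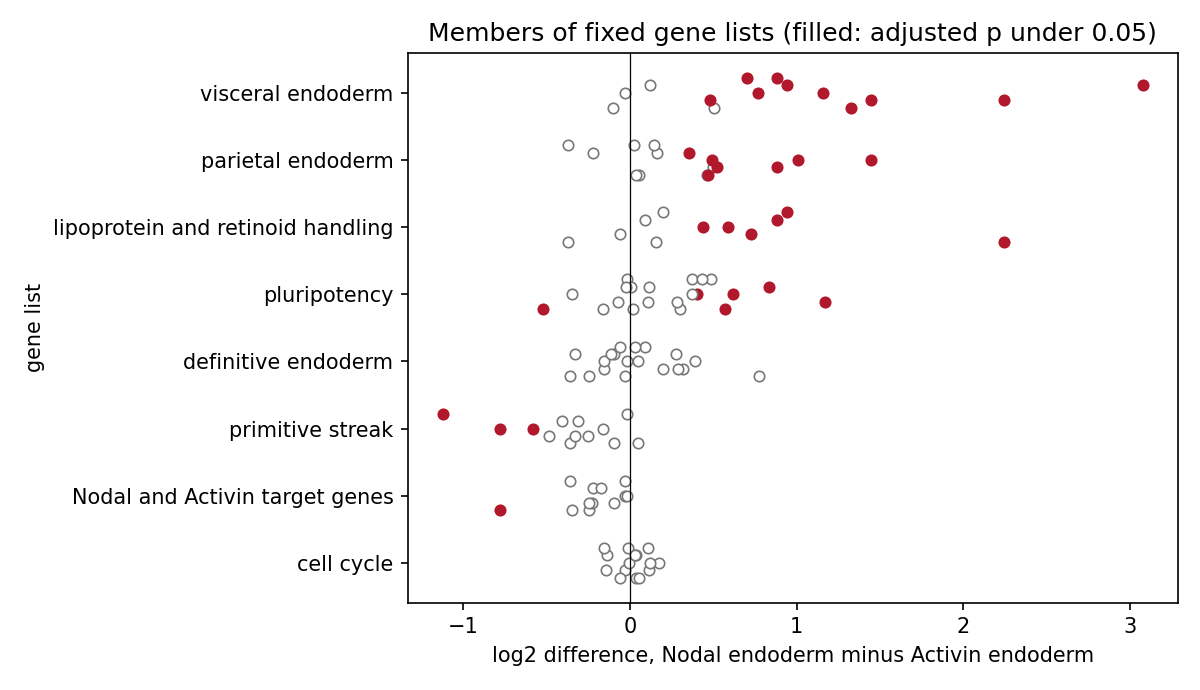
Log2 difference, Nodal endoderm minus Activin endoderm (x axis), of each tested member of 8 gene lists (y axis; small vertical offsets only separate points). Filled points had an adjusted p under 0.05. In the visceral endoderm list 10 points were filled, all above 0, and 0 of the 19 definitive endoderm genes were filled.

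The responses to the ligands were set against each other through the undifferentiated arrays that both comparisons share. Across genes, which are not independent replicates, the log2 changes correlated at r = 0.9873 (Spearman's rho = 0.9806), where unchanged groups simulated against the same controls gave a median r of 0.5. The covariance was 1.503 against a simulated 0.0054, a difference of 1.498. The sign was the same for 93.7% of genes, against 66.7% in the simulation. Of the genes, 3486 were higher and 3531 lower in both groups, where independent lists would share 1401 and 1455. The controls are 2 arrays and were not split, so part of the excess may come from sharing them. A further 526 genes passed with Activin alone and 578 with Nodal alone, which does not show that they differ between the ligands. Direction was opposite for 7 genes, by the probe used for each. Among them, Acta2, Dusp2 and Krt14 were higher with Activin and lower with Nodal, and Dab2, Mt1 and Rcsd1 the reverse. Only the probe used for Acta2 rose with Activin, while all 4 of its kept probes fell with Nodal, and Dusp2 and Krt14 were not detected with Nodal.

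**Figure D3:**
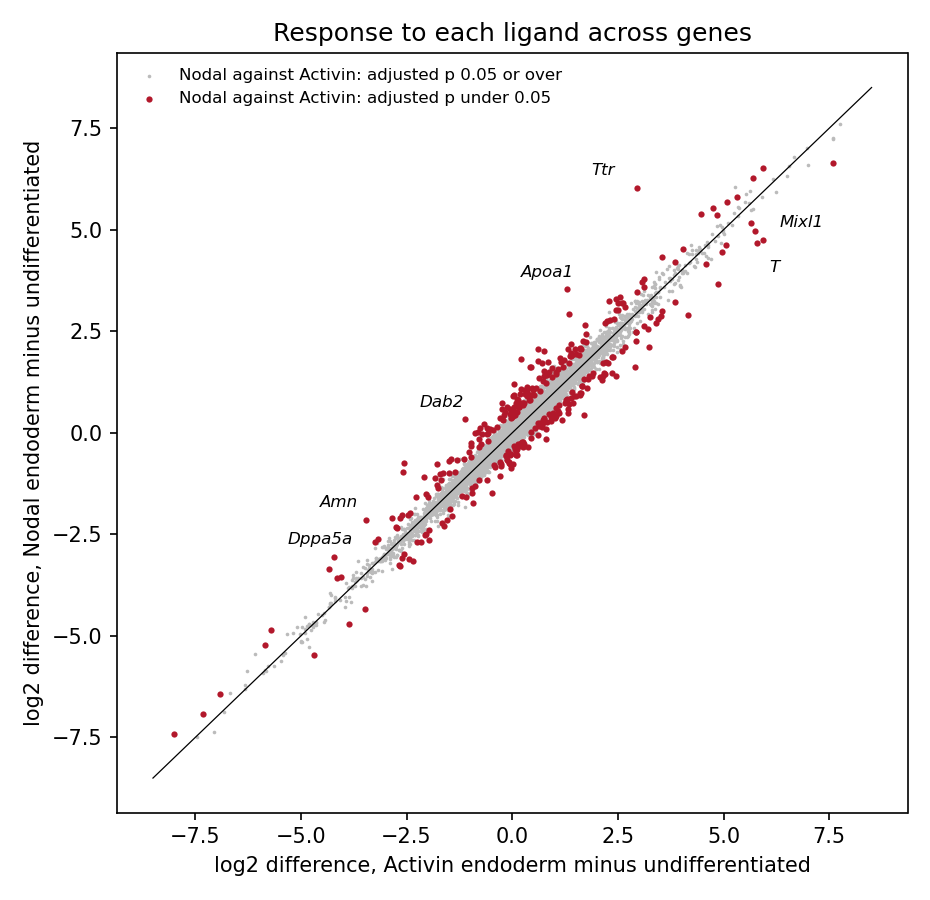
Fitted log2 difference from undifferentiated cells in Activin endoderm (x axis) and Nodal endoderm (y axis) for each of the 10050 genes, with the line of equal response; positions of genes not detected in a group, such as T and Apoa1 in undifferentiated cells, are uncertain. Red points mark the 328 genes with an adjusted p under 0.05 between the endoderm groups; Ttr (2.95 and 6.03) and Apoa1 lie above the line and T below it.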

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

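All tests of explanations in this part were chosen after the results were seen; the differences between the endoderm groups themselves were among the tests planned. A gene was singled out where both endoderm groups passed the threshold in opposite directions from undifferentiated cells and the difference itself passed in limma. The endocytic adaptor Dab2 stood out, since it was lower with Activin (-1.11 log2, adjusted p = 4.84e-06) and higher with Nodal (0.34, adjusted p = 0.0121), a difference of 1.45 log2 (SE 0.10, adjusted p = 0.000176). Of 14 other settings, 1 ended its small rise with Nodal and 0 ended the difference. The other genes given here moved less, and some of their calls ended under other settings. The difference was 0.55 log2 for Mt1 (adjusted p = 0.0102), 0.65 for Rcsd1 (adjusted p = 0.0075), -0.55 for Acta2 (adjusted p = 0.013), -0.60 for Dusp2 (adjusted p = 0.00856) and -0.73 for Krt14 (adjusted p = 0.0102). Each of these 5 differences ended without Nodal replicate 2, Rcsd1 (0.62, adjusted p = 0.0637) there alone; the others ended also without Activin replicate 2 and without Nodal replicate 1. Dusp2 and Krt14 were not detected in Nodal endoderm, so their fitted differences are uncertain; as bounds, Activin endoderm was brighter for Dusp2 at least 1.44-fold and Krt14 at least 1.36-fold. The rise of Acta2 with Activin was seen with 1 of its 4 kept probes, and its mean over probes was 0.11 log2 (adjusted p = 0.331). These genes were chosen after their values were seen.

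The higher visceral endoderm genes in Nodal endoderm raised the question of undifferentiated cells left among the reporter-positive cells, although selecting for the Sox17 reporter would remove such cells. Mixing can lift a gene at most to its level in undifferentiated cultures. Yet 7 of the 10 genes lay above both other groups past the threshold, Ttr, Apoa1, Apoa2, Dab2 and Hnf4a among them. These 5 passed between the endoderm groups under every setting that tested them, while Rbp4 and Spink1 did not. Apoa2 is near the floor, at 4.56 log2 in undifferentiated cells, 4.42 in Activin and 5.19 in Nodal endoderm. The lowest detected signal of an array was 4.99 to 5.06 log2. The other 3, Amn, Rhox5 and Apom, would need shares of 15%, 27.7% and 100% undifferentiated cells (median 27.7%), and Apom is near the floor. The reference was 12 other genes at 11 log2 or over in undifferentiated cells and at least 4 log2 above Activin endoderm. The share they needed had a median of 0.0315% and ran from -1.71% to 1.2%, where a share below 0 means a lower signal in Nodal than in Activin endoderm. In a wider set of 41 (limits of 10 and 3 log2), chosen after the shares were seen, it had a median of -0.0144% and ran from -3.27% to 5.05%. None of the 3 genes meets either rule: Amn lay at 9.65 log2 in undifferentiated cells, and Rhox5 at 10.09 against 8.38 in Activin endoderm. The 3 were also chosen for being higher in Nodal endoderm, unlike the reference genes. Lying above the reference was thus partly built in, and these shares decide little. Cells of the extraembryonic endoderm, in which Sox17 is also known to be active so that the reporter need not remove them, may be the source. The parietal endoderm list rose too (camera adjusted p = 9e-07, and 0.154 with an estimated correlation). Of its 7 called genes, however, Dab2 alone passed under every setting, and the lists share Dab2. No array of such cells is among those analysed. This source and an effect of the ligand or its dose, which was not tested, cannot be told apart.

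For the 5 pluripotency genes higher in Nodal endoderm, undifferentiated cells stayed open as a possible explanation. The shares needed had a median of 1.54% and ran from 0.201% (Esrrb) and 0.945% (Pou5f1) through 1.54% (Fbxo15) to 7.06% (Dppa5a) and 9.58% (Tbx3). The first 2 lie within the range of the 12 other genes, and Fbxo15 lies above it but within that of the wider set. Dppa5a and Tbx3 lie above both. Both ranges spread to either side of 0, so lying within them does not show that undifferentiated cells were present. Tbx3 meets neither rule for these sets, at 11.01 log2 in undifferentiated cells and 8.41 in Activin endoderm. The 5 genes were chosen for being higher in Nodal endoderm, unlike the reference genes, so lying above the sets was partly built in. No error was computed for these shares, so whether 1 share could account for all 5 stays open. An effect of the ligand or its dose was not tested.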

How the results depend on the processing

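All settings of this part were planned, and none was chosen after the results were seen. Some genes they were run on were chosen later. These are the genes called in opposite directions and the members of lists put together after the results were seen, Irgm1 and Mme among them. The count of genes that differed between Nodal and Activin endoderm (328) depended most on the settings: 528 with normexp by maximum likelihood, 114 without a filter on dim probes, 202 with detection on all 6 arrays, 90 at an adjusted p under 0.01, 26 with a 2-fold minimum, and 83 to 252 when 1 array was left out, the lone array then being assumed to vary like the other groups. A 2-fold minimum left 2748 genes for Activin and 2824 for Nodal against undifferentiated; each other setting kept those counts within 1.5 times. The correlation of the Activin and Nodal responses lay between 0.982 and 0.9874 when 1 array was left out. Of 66 pairs of list and comparison 36 passed. With an estimated correlation 0 of 66 passed (lowest adjusted p = 0.0893), but that test, on 3 residual degrees of freedom, could hardly pass. For the visceral endoderm list between the endoderm groups the correlation was estimated at -0.047, below the preset 0.01. Even so, its unadjusted camera p was 0.00261, against 1.93e-18 with the preset. Without genes shared by lists 20 of 60 passed, and 12 calls ended. With fry, which does not compare a list with other genes, 51 of 66 passed, 35 of those 36 among them. The midgut and hindgut list turned its direction with fry (adjusted p = 0.0037 with Activin and 0.00321 with Nodal), where its mean and median have opposite signs. Among list members, the mean over probes turned Hspa8 (-0.58) and Tpi1 (-0.36) with Activin and Irgm1 (0.92) with Nodal, and median scaling turned Mme (0.013) with Nodal; the cause was not tested. Over all named genes and list members, 13406 values were labelled unchanged, 406 lost the call, 172 gained one and 463 moved. Where a setting gave a p, unchanged means the same direction and side of the threshold, and moved means a changed sign without a call. The submitters' averaged values, which have no p, gave 747 of the unchanged and 250 of the moved values. There unchanged means within 1 standard error of the fitted difference, and moved means beyond it. With the replicate number as a block the counts were 7597, 7666 and 320. Deviations of same-numbered arrays correlated at 0.003 (undifferentiated with Activin), 0.028 (undifferentiated with Nodal) and 0.11 (Activin with Nodal). A weak shared effect could give such values too, so whether the numbers pair the arrays stays unknown. A slide block was not run. Signal over background limits the dimmest genes; where a gene was not detected in a group, its fitted difference is uncertain.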

Other observations

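All tests in this part were chosen after the results were seen, on lists put together from genes that differed between the endoderm groups; only members that had not prompted a list were tested. The list of the microvillar border of absorptive epithelia was prompted by 7 genes higher in Nodal endoderm, among them Dpp4, Amn and Muc13. Vil1, an actin bundler, was higher by 1.16 log2 (SE 0.08, adjusted p = 0.000178), and the motor gene Myo6 by 0.89 (SE 0.11, adjusted p = 0.00311). The scaffold gene Pdzd3, not detected in Activin endoderm, was at least 1.46-fold brighter (adjusted p = 0.00122). The calls of Vil1 (0.63 log2 with normexp by maximum likelihood), Myo6 and Pdzd3 passed under every setting tried, while that of Myo7a (0.72 log2, adjusted p = 0.0178; detected on 1 of 2 Activin arrays) ended without Activin replicate 2 (0.53, adjusted p = 0.0958), Nodal replicate 1 (0.64, adjusted p = 0.127), Nodal replicate 2 (0.77, adjusted p = 0.0685) or the filter on dim probes (adjusted p = 0.0983), and that of Muc13 ended where leaving out a Nodal array also exchanged its probe. A wider brush border programme may be higher in Nodal endoderm: the other 10 members were higher as a list (camera adjusted p = 0.0144). They did not pass with an estimated correlation (adjusted p = 0.327), a test on 3 residual degrees of freedom with little power. Of these members 1, Mttp, passed alone (0.59 log2), a call that ended without Activin replicate 2 (0.41 log2) and in 7 other settings. Mttp also belongs to the fixed lipoprotein and retinoid list, where its rise was already counted, and the other members were not tested without it. The hypothesis stays open.

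For 3 other lists the members past the threshold were those that prompted the list, and the other members did not pass as a list. Leaving out every member past the threshold made a pass less likely, so these tests do not exclude a shift of a whole list. Interferon response and antigen processing was prompted by 9 genes lower in Nodal endoderm such as Psmb10 (-0.68 log2), and its other 23 members gave an adjusted p of 0.207 (0.423 with an estimated correlation). The sarcomere was prompted by 4 genes higher in Nodal endoderm such as Myl4 (0.97 log2). Its other 9 members, with a median of -0.10 log2, gave an adjusted p of 0.0852 (0.327 with an estimated correlation). The direction of these members was down, opposite to that of the prompting genes. Enteroendocrine genes were prompted by Sst, Ghrl, Rfx6 and Pyy, of which Pyy missed the threshold (adjusted p = 0.0614), and the other 11 members gave an adjusted p of 0.943 (0.953 with an estimated correlation). The call of Psmb10 ended without Activin replicate 2 (adjusted p = 0.0704), Nodal replicate 2 (adjusted p = 0.0852) or the filter on dim probes (adjusted p = 0.0594), and that of Myl4 without Activin replicate 2 (adjusted p = 0.0719), Nodal replicate 1 (adjusted p = 0.0508) or that filter (adjusted p = 0.0689).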
